A study of Drosophila melanogaster with 3 samples.

How the data were processed

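The study measured where a tagged Lhr protein sits on DNA in Drosophila melanogaster embryos by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Lhr (Lethal hybrid rescue) is known as a chromatin protein that acts together with Hmr (Hybrid male rescue) and with heterochromatin protein 1. Per the labels, whole embryos of both sexes, 0 to 14 hours old, came from a transgenic line that stably expresses Lhr with eGFP at its C-terminal end, chromatin was sonicated to fragments of 200 to 800 bp, and the tagged protein was recovered with an antibody against GFP. The 3 libraries are biological replicates 1, 2 and 3 of 1 group, per the labels. There is no second group, so every comparison is made within this group, against rotated positions, flanking sequence or other genes. The control library that the labels name is not analysed here.

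The deposited files are peak lists in narrowPeak format. Per the labels and the text listings that came with each library, a relaxed list of peaks and background was made for each library from its alignment and a single control alignment shared by all 3 libraries. A combined relaxed list was made for the experiment. A final list was derived from these by thresholding on the irreproducible discovery rate (IDR), a measure of how alike peaks rank in replicates. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each list exists for the assemblies dm6 and dm3, and positions were never converted between them. The deposited signal value of a peak is the authors' own enrichment value, which ranks peaks within a list and has no common scale between lists. The deposited −log10 q-value runs from 2.45 to 3.70 in the IDR list for dm6, where many peaks share the highest value, and was not used for ranking. The deposited p-value column holds no values. The last deposited column gives the distance from the start of a peak to its summit.

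The dm6 IDR list holds 5190 peaks and is identical to the 5190 peaks of highest signal in the combined relaxed list. It thus amounts to a cut on combined signal, and a single peak in it need not recur in every library. Replicates 1, 2 and 3 have relaxed lists of 22598, 30000 and 18934 peaks. The round length of the list of replicate 2, also 30000 for dm3, has the look of an upper limit on list length, and no source used here states one. Read depth is unknown, because the lists hold no read counts, so no interval for a peak can be given. Signal tracks were not used here. Most peaks have one fixed width, 430 bp for 67.1% of IDR peaks, so a peak is treated as its summit, and widths are not interpreted.

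Each library entered the comparisons through its 5190 peaks of highest signal, so that lists of equal length were compared. Genome sequence and gene models were those of Release 6, the same assembly as dm6, with Ensembl gene models that carry FlyBase identifiers. Summits within 500 bp of any annotated start site were called promoter peaks, and the others were placed in the first of 5′ UTR, coding exon, 3′ UTR, intron, noncoding exon and intergenic sequence that applied. A protein-coding gene was called bound when a summit lay within 500 bp of one of its start sites. Positions were tested against 10000 circular rotations of all summits along the joined arms 2L, 2R, 3L, 3R, 4, X and Y, which keep the spacing between peaks (permutation tests, two-sided except for the overlap of replicates). The smallest p these rotations can give is 2.0e-04 two-sided and 1.0e-04 one-sided. Pericentric parts began at 22 Mb on 2L, 23 Mb on 3L and 22 Mb on X, and ended at 5.4 Mb on 2R and 4.6 Mb on 3R. Motifs were exact matches to 15 consensus words on either strand within 100 bp of a summit. They were compared by two-sided Fisher's exact tests with windows 1000 bp to each side that lay over 300 bp from any IDR summit. Where promoter and distal peaks were taken apart, these windows were kept clear of summits of the same class only. Gene sets were compared with all other protein-coding genes by two-sided Fisher's exact tests. They were 18 named lists, the genes of chromosome 4, the genes inside the pericentric borders, and tRNA genes. All p-values of a family were adjusted by the Benjamini-Hochberg method. Tests over peaks or genes treat them as independent, which they are not, so the share in each library is given beside them as mean ± SD (n = 3).

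The lists, motifs, borders, tests and the rule for naming genes were fixed before the data were examined. The rule names the nearest protein-coding gene of each of the 15 strongest IDR peaks, up to 4 bound members of each list by signal and up to 2 unbound members in alphabetical order, and Lhr, Hmr, Su(var)205 (the gene of HP1a) and BEAF-32 in any case. The names scarface and Nsl1 in the lists matched no gene and were left out. Alternatives were a stricter list, the combined list, peaks shared by all libraries, each library left out in turn, which keeps the peaks shared by the other 2, other windows and borders, other backgrounds and the dm3 lists. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

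The tests were checked on simulated data. On 5190 peaks rotated by a random step, the promoter and the pericentric tests made 0 calls each in 20 draws. These peaks were drawn in the same way as the background, so this checks the computation only. It cannot show whether rotation is a fair background. The simulated position tests used fewer rotations than the main tests. With 10 percent of the peaks moved to promoters, the promoter test made its call in 20 of 20 draws. With bound genes drawn at random among 13968 protein-coding genes, 0.238% of 2100 list tests were called. Genes were drawn independently, so summits shared by neighbouring genes are not covered by this check. Cytoplasmic ribosomal proteins bound at 2 times the rate were found in 100 of 100 draws. No effect was planted in the smaller lists, so how often one would be found there is not known. With M1BP written into 2 percent of windows out of 9794, the motif test found it in 20 of 20 draws.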

Results

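Lhr-eGFP was recovered from 0 to 14 hour embryos in 3 replicate libraries, and the final list held 5190 peaks on dm6. Of these, 948 lay on 2L, 1021 on 2R, 1101 on 3L, 1190 on 3R, 860 on X, 69 on chromosome 4 and 1 on Y. The list for the older assembly dm3 held 4956 peaks. The depth of the libraries is unknown.

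The first question was how far the replicates recovered the same places. Between pairs of libraries, 73.9% ± 2.82 (SD, n = 3 pairs) of the 5190 strongest peaks had a counterpart summit within 100 bp. The shared part was 71.0% for replicates 1 and 2, 76.7% for replicates 1 and 3, and 74.0% for replicates 2 and 3. Rotated peaks shared about 0.758%, and each pair exceeded all rotations (adjusted p = 1.0e-04, one-sided permutation test, the smallest possible). Of the IDR peaks, 64.3% lay among the strongest peaks of all 3 libraries. The 15 strongest IDR peaks were all found there. The libraries were called against 1 shared control alignment, so part of this overlap may come from that control, which cannot be split here. The lists without replicate 1, 2 or 3 keep only peaks shared by the other 2 libraries and are shorter (3842, 3980 and 3687 peaks), so a call lost there is not put down to the replicate.

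The strongest peaks lay at scattered single places, and 6 of the 15 were at promoters, 4 in intergenic sequence, 3 in introns and 2 in 3′ UTRs. The highest signal, 5492.0, was at X 796258 to 797111, in the 3′ UTR of CG16989. The second, with a signal of 4920.8, was at 2L 2193309 to 2193875, in an intron of COX7AL2. The third lay in intergenic sequence at 2L 4809968 to 4810473, 2783 bp from the start of CG15629. The fourth, at 2L 12007256 to 12007801, lay 638 bp from the start of Rh5, a rhodopsin of photoreceptor cells. The fifth was in the 3′ UTR of lwr, the E2 enzyme that conjugates SUMO, at 2L 540422 to 541405. The others had as nearest genes CG5273, CG15468, spok, hll, px, Ugalt, CG14100, cbt, CG11050 and CG6966. The peak assigned to spok, a gene of ecdysone synthesis, was at 3R 3374105 to 3374580 in pericentric sequence, 51526 bp from the gene's start site.

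Where Lhr-eGFP lay relative to genes was asked next. Promoters held 64.0% of the IDR summits, 3321 of 5190, against 13.3% ± 0.662 (SD of rotations) for rotated peaks, a 4.82-fold excess (adjusted p = 2.8e-04, two-sided permutation test). In the libraries the promoter share was 64.2% ± 4.93 (SD, n = 3), with 59.5% in replicate 1, 69.3% in replicate 2 and 63.7% in replicate 3. Coding exons were almost free of summits, with 0.289% against 13.4% for rotated peaks. Introns held 21.3% against 39.3%, intergenic sequence 12.5% against 28.4%, and 3′ UTRs 0.983% against 4.31%, all lower with the same adjusted p, which rests on the smallest p the rotations can give. The share in 5′ UTRs outside promoters, 0.462% against 0.760%, was also lower (adjusted p = 0.0191, permutation test), but not without replicate 2 (0.477%, adjusted p = 0.0558). Noncoding exons did not pass the test (0.520% against 0.609%, adjusted p = 0.525, permutation test). Each summit counts in a single class and promoters come first, so the promoter excess by itself lowers the other shares. These classes were not compared among the summits outside promoters alone.

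Within promoters the summits sat just upstream of the start site. Of the 3202 summits within 500 bp of a protein-coding start site, 89.2% lay upstream and 55.9% lay within 100 bp. The median position was −82 bp in the IDR list, and −86, −78 and −79 bp in replicates 1, 2 and 3. Stronger peaks were more often at promoters, with 72.4% of the 519 strongest IDR peaks and 51.1% of the 519 weakest, a trend that was not tested and did not extend to the 15 strongest peaks, of which 6 were at promoters.

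**Figure D1:**
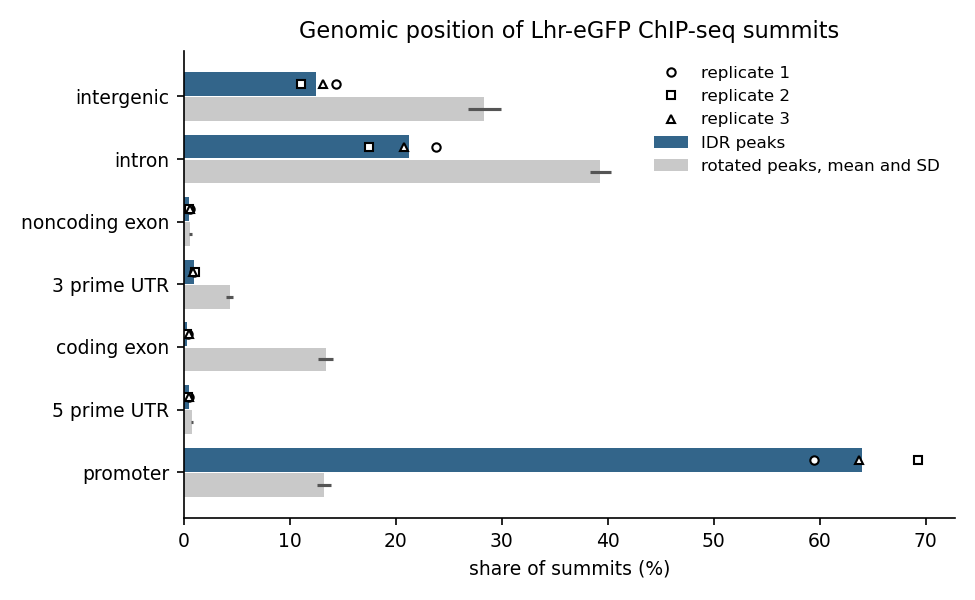
Share of summits (%) in each class of sequence. Dark bars are the 5190 IDR peaks, grey bars the mean and SD of 10000 rotations, and symbols the 5190 strongest peaks of each library. Promoters held 64.0% of IDR summits against 13.3% of rotated ones.

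**Figure D2:**
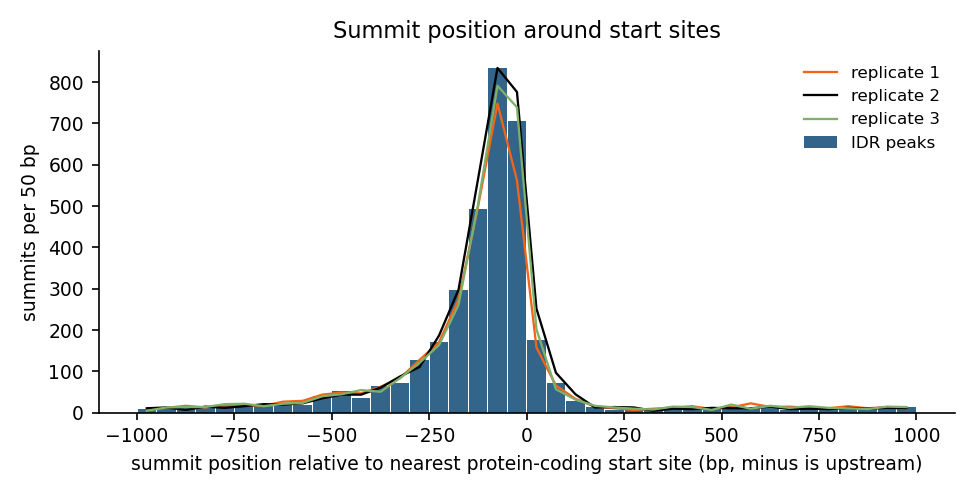
Number of summits per 50 bp by position relative to the nearest protein-coding start site (bp, negative values upstream). Bars are IDR peaks and lines the 3 libraries. In each the median of summits within 500 bp lay between −86 and −78 bp.

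Lhr is known as a heterochromatin protein, and the next question was whether the peaks gathered on heterochromatic arms or near centromeres. No arm passed the test for a higher density, and pericentric sequence as a whole had a lower one. Chromosome Y, which is almost wholly heterochromatic, held 1 peak, a density 0.00723 times that of all arms (adjusted p = 0.0140, two-sided permutation test), and 0 peaks without replicate 1 or replicate 3 (adjusted p = 0.0182). Chromosome 4 held 51.2 peaks per Mb, 1.36 times the density of all arms, which did not pass the test (adjusted p = 0.977, permutation test), and neither did the other 5 arms. The ratio for chromosome 4 was 1.35 ± 0.119 (SD, n = 3) in the libraries. Pericentric sequence held 238 peaks in 18.2 Mb, or 13.1 per Mb, against 42.7 per Mb in the rest of the 5 long arms. The ratio of 0.307 lay below that of rotated peaks (p = 0.0170, permutation test), with 0.360 ± 0.106 (SD, n = 3) in the libraries. Of the 238 pericentric peaks, 115 were at promoters, 67 in intergenic sequence and 49 in introns. Counting only bases outside transposons and soft-masked repeats, a setting chosen after the data were seen, raised the ratio to 0.451 and ended the call (p = 0.0514, permutation test). Reads from repeats are hard to place, and no correction for this was made on Y. Nor was any made for the copy number of X and Y in embryos of both sexes. The dm3 list has no Y, and there 0 arms passed the test, with 1 of them, X, at an unadjusted p of 0.0416 (permutation test).

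Genes in heterochromatic surroundings were nevertheless bound more often than others. Of the 13968 protein-coding genes, 4085 (29.2%) were bound, with 28.9% ± 2.33 (SD, n = 3) in the libraries. Of the 247 genes inside the pericentric borders, 100 (40.5%) were bound, against 29.0% of the others (adjusted p = 3.6e-04, Fisher's exact test). On chromosome 4 it was 42 of 80 genes (52.5%, adjusted exact p = 5.4e-05). Among 27 well-known genes embedded in pericentric heterochromatin, 15 were bound (55.6%, adjusted exact p = 0.00723). They included p120ctn, a catenin, with a summit 38 bp from its start, Nipped-B, the cohesin loader, at 39 bp, the RNA helicase gene Dbp80 at 67 bp, and RpL5 at 87 bp. AGO3, which encodes a piRNA-binding Argonaute, was bound in 0 of 3 libraries. The call for the embedded genes was lost in the shorter lists without replicate 1 (40.7% against 24.5% of other genes, adjusted exact p = 0.0980) and without replicate 3 (40.7% against 22.5%, adjusted exact p = 0.0568).

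Genes for cytoplasmic ribosomal proteins and for RNA polymerase II transcription had the highest bound shares of the 21 gene sets. In all, 10 sets were bound more often than other genes, 5 less often, and 6 did not pass the test. Of the 92 cytoplasmic ribosomal protein genes, 79 (85.9%) were bound, with 85.5% ± 5.36 (SD, n = 3) in the libraries (adjusted p = 2.3e-28, Fisher's exact test). Their strongest summits were at RpL30 (rank 25 of all peaks, 55 bp from the start, 2L 19009361), RpL23A (rank 32), RpL7 (rank 76) and RpLP2 (rank 132). RpL10Ab was not bound in the IDR list, although 2 of the 3 libraries placed a summit there and it was bound without replicate 1 (44 bp), and RpL10Aa was bound in 0 of 3 libraries. Of the 35 genes of the RNA polymerase II transcription machinery, 30 (85.7%) were bound, with 80.0% ± 7.56 (SD, n = 3) in the libraries (adjusted p = 1.9e-11, Fisher's exact test). Examples were TfIIA-S, MED21, TfIIEalpha and Taf1, each with a summit within 82 bp of a start site, while MED14, which was bound without replicate 1 (65 bp), and MED8 were not bound. Of 73 mitochondrial ribosomal protein genes, 36 were bound (49.3%, adjusted exact p = 7.0e-04), led by mRpS10 at rank 26 and mRpL41 at rank 36. Proteasome subunits had 22 of 48 (45.8%, adjusted exact p = 0.0227), among them Prosalpha5, Rpn6, Prosbeta3 and Rpn13, but lost the call with a window of 1000 bp (45.8% against 32.1% of other genes, adjusted exact p = 0.0633). With the upper 50 percent of IDR peaks by signal, 2595 peaks, 17.2% of other genes were bound, and mitochondrial ribosomal proteins (26.0%, odds ratio 1.70, adjusted exact p = 0.105) and proteasome subunits (25.0%, odds ratio 1.61, adjusted exact p = 0.265) lost their calls but not their direction. Among genes without a divergent neighbour, a setting chosen after the data were seen, 26 proteasome genes were left and lost the call (34.6% against 18.1% of other genes, adjusted exact p = 0.0587), although their odds ratio was 2.40, against 2.05 among all genes. Mitochondrial ribosomal proteins fell to 17.6%, against 18.1% of other genes (adjusted exact p = 1).

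Genes of chromosome structure and of cell division were also bound often. Of 34 DNA replication and cell cycle genes, 22 (64.7%) were bound, with 62.7% ± 1.70 (SD, n = 3) in the libraries (adjusted p = 7.0e-05, Fisher's exact test). CycB, a mitotic cyclin, had the strongest summit of this list (rank 138), followed by Dp, dup and Mcm7, and Mcm3 was not bound. Cdk2 was not bound in the IDR list, although it was bound in 2 of the 3 libraries and without replicate 2 (46 bp). Of 18 insulator and boundary factor genes, 13 (72.2%) were bound (adjusted exact p = 3.8e-04). Chro, a protein of interbands and the mitotic spindle, had the highest signal among them (rank 19, 3L 22878908, 76 bp from its start), followed by Clamp, Cp190 and pzg. Elba2 and Trl were bound in 0 of 3 libraries. In the libraries the insulator list was bound at 57.4% ± 6.42 (SD, n = 3), each below the IDR value, and its call was lost in the shorter lists without replicate 2 (38.9% against 23.1% of other genes, odds ratio 2.12, adjusted exact p = 0.218) and without replicate 3 (44.4% against 22.5%, odds ratio 2.75, adjusted exact p = 0.0638), from an odds ratio of 6.31 in the IDR list. Of 19 centromere and kinetochore genes, 12 (63.2%) were bound (adjusted exact p = 0.00581), among them the spindle checkpoint genes mad2 and Mad1 and the kinetochore genes Spc105R and Nuf2. That call was lost in the shorter list without replicate 3 (42.1% against 22.5% of other genes, adjusted exact p = 0.0743). Among the 3291 peaks shared by all 3 libraries, the insulator (38.9%, adjusted exact p = 0.103) and centromere lists (42.1%, adjusted exact p = 0.0592) lost their calls, against 20.5% of other genes. With the upper 50 percent of IDR peaks these lists (27.8% and 36.8%, adjusted exact p = 0.306 and 0.0625) and the replication list (29.4%, adjusted exact p = 0.110) lost theirs, each still above the 17.2% of other genes (odds ratios 1.85, 2.81 and 2.01). Among promoters without a core promoter word, a setting chosen after the data were seen, the insulator list kept 9 genes and missed the threshold (55.6% against 23.1% of other genes, adjusted exact p = 0.0502).

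Summits within 500 bp of a start site were rare at genes of pattern formation, of the cuticle and of the senses. Peaks farther from a start site do not count here. Distal peaks lay nearest to the patterning genes slp2, odd and ems, for example. Of 43 developmental patterning genes, 2 were bound (4.65%, adjusted p = 1.8e-04, Fisher's exact test), namely bcd, with a summit 211 bp from its start, and tin, at 245 bp. The Hox genes Abd-B and Antp were not bound in the IDR list or in any library. This list lost its call with the upper 50 percent of IDR peaks (4.65% against 17.2% of other genes, adjusted exact p = 0.0524) and, in a setting chosen after the data were seen, among genes without a divergent neighbour (5.13% against 18.2% of other genes, adjusted exact p = 0.0567). Of 179 olfactory, gustatory and ionotropic receptor genes, 2 were bound (1.12%, adjusted exact p = 4.4e-23), Ir60b in 3 libraries and Gr63a in 2, the latter lost without replicate 2 or replicate 3, which left 0.559% of the list bound. None of 95 cuticle protein genes was bound (adjusted exact p = 3.1e-14), and replicate 1 alone placed a summit at 1 of them. Of 290 tRNA genes, 18 were bound (6.21%, adjusted exact p = 1.6e-21), and without replicate 3 it was 3.45% (adjusted exact p = 1.1e-18). This share was 1.38% with a 200 bp window and with the upper 50 percent of IDR peaks, and 11.4% with a 1000 bp window, each still lower than in other genes. None of the 111 replication-dependent histone genes was bound. That value is uncertain, because these genes are near-identical copies in a cluster at 2L 21416953 to 21541681, and none of the relaxed lists held a peak there.

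The other lists did not pass the test. Genes for HP1 family and heterochromatin proteins were bound at 10 of 22 (45.5%, adjusted p = 0.127, Fisher's exact test), with G9a, sov, Su(var)3-7 and ADD1 bound and HP1b and HP1c not bound. The piRNA pathway had 9 of 24 (adjusted exact p = 0.437), heat shock 6 of 17 (adjusted exact p = 0.643), telomere capping 3 of 11 (adjusted exact p = 1), neuronal function 3 of 24 (adjusted exact p = 0.0989) and muscle 4 of 18 (adjusted exact p = 0.643). The piRNA pathway's share of 37.5% was 20.8% without replicate 2, against 23.1% of other genes (adjusted exact p = 1). Bound members included vas and papi, Hsp83 and Hsc70-4, tefu and ver, of which tefu and Hsc70-4 share 1 summit, elav and Syx1A, and Tm1 and sls. HipHop, tej and Hsc70-3 were bound in the IDR list and in 1 of 3 libraries, and so in no list of peaks shared by 2 libraries. Lhr itself had a weak summit 46 bp from its start (rank 4100, 3 of 3 libraries), and BEAF-32, an insulator protein gene, had one at 96 bp (rank 3479, 3 of 3 libraries). Hmr, the partner gene, was not bound in the IDR list or in any library, and the gene of HP1a was bound in 1 of 3 libraries but not in the IDR list.

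**Figure D3:**
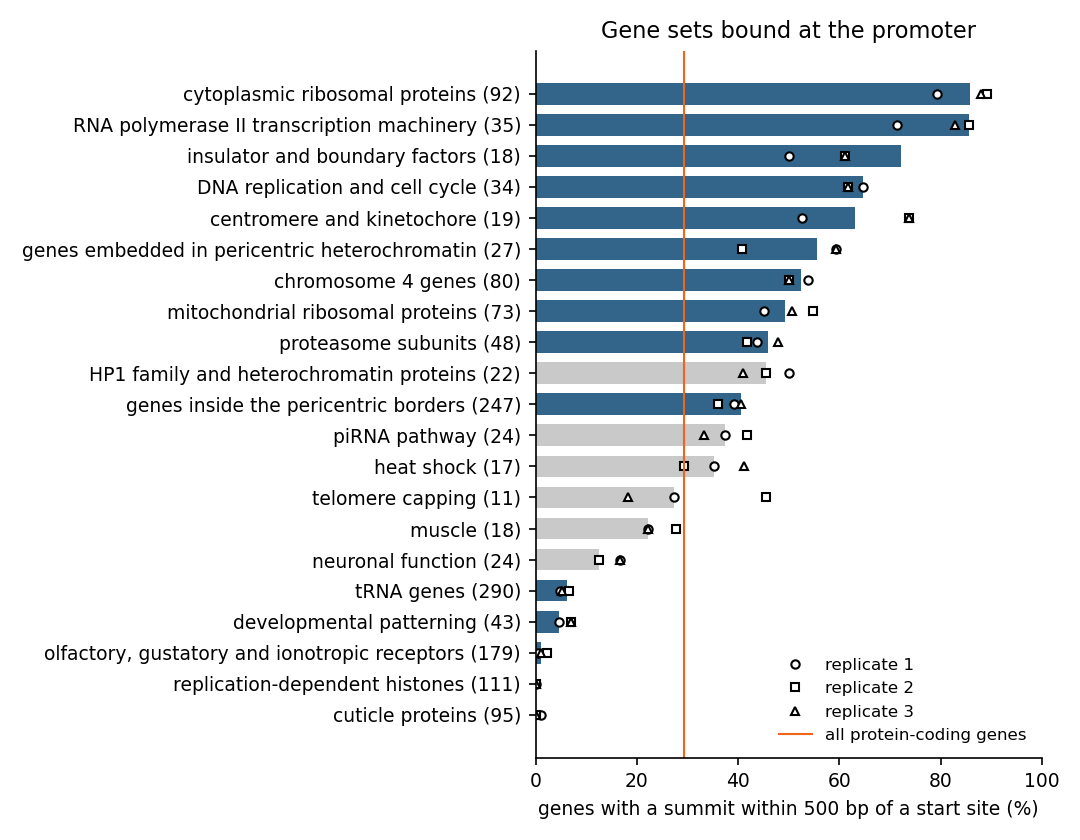
Share of genes (%) with an IDR summit within 500 bp of a start site, for each gene set with its size in brackets. Blue bars passed an adjusted p of 0.05, grey bars did not, symbols are the 3 libraries and the line marks the 29.2% of all protein-coding genes. Cytoplasmic ribosomal proteins reached 85.9% and cuticle proteins 0%.

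The next question was whether bound promoters lay between divergent genes, since HMR and BEAF-32 sites have been described at borders between genes. Among bound protein-coding genes, 60.5% (2471 of 4085) had a gene on the opposite strand starting within 1000 bp upstream, against 26.2% (2587 of 9883) of unbound genes. The odds ratio was 4.32 (p = 1.7e-315, two-sided Fisher's exact test), and the share was 60.3% ± 0.559 (SD, n = 3) in the libraries. A summit between 2 divergent genes counts for both. With each summit given to its nearest gene alone, a setting chosen after the data were seen, 49.8% of bound genes were divergent (p = 2.8e-65, Fisher's exact test). That setting moves partners of shared summits to the unbound genes, so the 26.2% above is not its comparison. Its own unbound share is not given here.

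The last question was which known sequence elements lay under the peaks. The motifs of M1BP and DRE, elements of housekeeping promoters, had the highest excess over flanks, followed by that of CTCF. M1BP's motif, GGTCACACT, was present in 6.59% of summit windows against 0.153% of flanking windows, a 43.0-fold excess (adjusted p = 7.0e-137, Fisher's exact test). The DRE or BEAF-32 palindrome TATCGATA was present in 7.21% against 0.429%, or 16.8-fold. Against unbound promoters these excesses were far smaller, with M1BP's motif in 11.7% of bound and 2.62% of unbound promoters (4.47-fold) and the DRE palindrome in 12.7% and 5.84% (2.17-fold), below CTCF (4.15-fold), Ohler 7 (3.12-fold) and Ohler 6 (2.98-fold). In this comparison each gene had 1 window, at its outermost start, although it counted as bound at any of its start sites. The window of a bound gene is therefore not always the bound promoter. The core promoter motifs Ohler 7 and Ohler 6 were present, against flanks, in 5.11% against 1.04% (4.90-fold) and in 5.39% against 1.31% (4.13-fold). The insulator motif of CTCF was present in 3.80% against 0.306% (12.4-fold), and that of su(Hw) in 2.00% against 0.674%. The short BEAF-32 word CGATA was found in 37.8% against 21.4%. In the libraries, M1BP's motif was found in 6.48% ± 0.774 and CTCF's in 3.63% ± 0.0779 of windows (SD, n = 3).

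Other elements were weaker or lower. The motif of Pho, a Polycomb recruiter, was in 4.37% against 3.46% (adjusted p = 0.00897, Fisher's exact test), and TATA boxes were in 15.7% against 10.5% (adjusted p = 3.2e-19). The repeated GAGA word was lower under the peaks than beside them, in 2.70% against 3.91% (adjusted exact p = 1.7e-04), as was that of the early embryonic activator Zelda, in 0.751% against 1.18% (adjusted exact p = 0.0186). The E-box did not pass the test (10.6% against 9.98%), but did with 200 bp windows (20.6%, adjusted exact p = 0.0152) and against unbound promoters (16.7% against 12.5%, adjusted exact p = 3.8e-10). The satellite repeats dodeca, AATAT and AAGAG had 0 matches under IDR peaks and 0, 2 and 0 in the 9794 flanking windows, too few to compare, and replicates 1 and 2 each held satellite matches (AAGAG and AATAT) in 0.0193% of windows. Against unbound promoters, in windows at gene starts and not at summits, the TATA box reversed, with 10.7% of bound and 20.7% of unbound promoters (adjusted exact p = 2.9e-48). Sites and background both changed there, so the reversal is not put down to either. With 200 bp windows GAGA reversed to 8.11% (adjusted exact p = 0.00338). Zelda's call was lost without replicate 2 (0.804%, adjusted exact p = 0.0921) and without replicate 3 (0.895%, adjusted exact p = 0.0802), and with 50 bp windows (0.501%, adjusted exact p = 0.707). Pho's was lost with 50 bp (2.14%, adjusted exact p = 0.0597) and 200 bp windows (7.98%, adjusted exact p = 0.0970), and that of su(Hw) against unbound promoters (0.710%, adjusted exact p = 0.168).

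Promoter and distal peaks held different elements. M1BP's motif was in 333 of 3321 promoter peaks and 9 of 1869 distal peaks (0.482%), and the DRE palindrome in 10.2% and 1.93% (adjusted p = 1.5e-53 and 7.9e-33, Fisher's exact test). CTCF's motif was instead in 5.62% of distal and 2.77% of promoter peaks (adjusted exact p = 1.0e-06), and that of su(Hw) in 3.16% and 1.36% (adjusted exact p = 3.3e-05). Of the 738 genes with M1BP's motif at the gene start, 64.9% were bound at any of their start sites. For the 2485 genes with a TATA box there it was 17.5%. In distal peaks alone, M1BP, Ohler 6, Ohler 7, CGATA, GAGA, Pho and Zelda lost their calls against flanks. Against these flanks the excess itself went for M1BP (1.23-fold), Ohler 6 (1.04-fold), CGATA (1.11-fold) and Pho (0.987-fold), and the deficit for Zelda (1.06-fold). GAGA (0.736-fold) stayed near its value of 0.690 over all peaks, and Ohler 7 was at 1.59-fold. The flanks of distal peaks were kept clear of distal summits only, so some could lie at promoter peaks. M1BP's motif was in 0.391% of them, against 0.153% of the flanks of all peaks. How much of the lost excess comes from these flanks was not tested. The split by peak class was chosen after the data were seen.

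**Figure D4:**
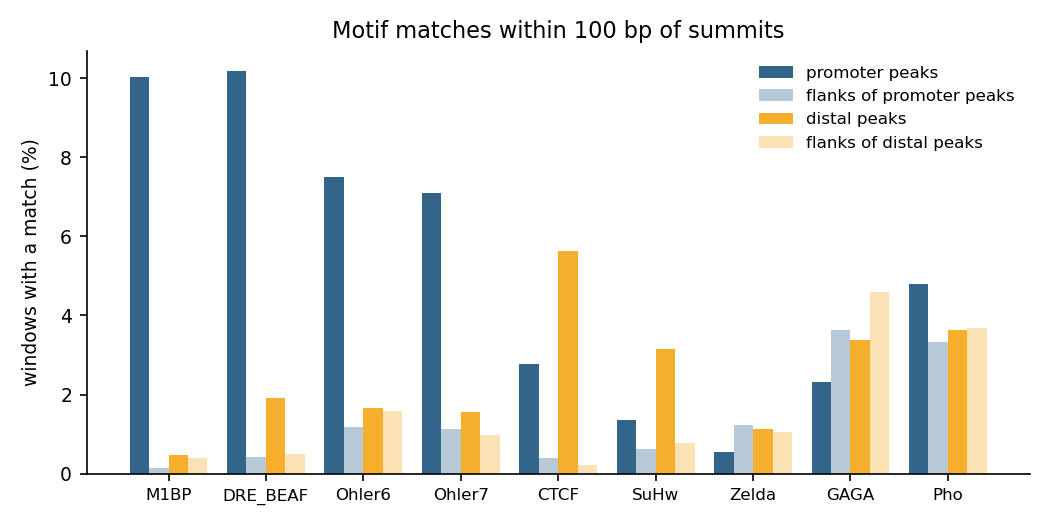
Share of windows (%) with a match to each motif within 100 bp of the summit, for promoter and distal IDR peaks (full colours) and for their flanks (pale colours). Flanks were kept clear of summits of the same class only. M1BP's motif was in 333 of 3321 promoter peaks, and CTCF's in 5.62% of distal peaks.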

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

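The promoter shares of each library's 1000 and 2595 strongest peaks were chosen after the data were seen. So were the settings without repeats, without divergent genes and without promoters that hold a core promoter word. The test of promoters inside the pericentric borders was chosen only after its result was seen. The dm3 lists held peaks on sequences that were not analysed here. Positions were not converted between assemblies, so whether the dm6 list holds the same places is not known. The final list held 75 peaks on heterochromatic and unplaced sequences that are separate from the long arms in that assembly, with 22 on 2RHet, 20 on 3LHet, 14 on 3RHet, 11 on U and 6 on Uextra. They made up 1.51% of that list, and such peaks made up 7.17% of the combined relaxed list. No dm3 sequence was used here, so these peaks were given no gene or motif.

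Pericentric sequence had 0.307 times the peak density of the rest of the long arms, and 46.4% of its bases are transposons or soft-masked repeats against 18.6% elsewhere. Over the remaining bases the ratio was 0.451 (95% block bootstrap interval 0.287 to 0.690), and for distal peaks outside promoter bases 0.508 (interval 0.312 to 0.801). Both intervals lie below 1, so a deficit remained over bases outside annotated repeats. The rotation test for all peaks over these bases did not pass (p = 0.0514, permutation test). The intervals are too wide to say how much of the deficit comes from repeats, in which reads are hard to place. That part cannot be told apart from lower recovery. Few promoters per Mb are consistent with the deficit of promoter peaks, because promoter bases made up 2.31% of pericentric and 15.4% of other sequence, while genes there were bound 1.39 times as often as others (interval 1.20 to 1.62). With 1 group, no biological explanation was tested.

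Ribosomal, transcription and cell cycle genes were bound far more often than receptor, cuticle and patterning genes. Promoters shared with a divergent neighbour could raise this, but 12 of the 15 called sets kept call and direction with such genes left out, which argues against them as the whole cause. Exact matches to M1BP, DRE, Ohler 6 or Ohler 7 are not the whole cause either. With protein-coding genes that hold one left out (tRNA genes were not filtered), 14 of the 15 sets kept call and direction. The 8 lists bound more often were bound in 128 of 203 genes without a word (63.1%) and 98 of 140 with one. In 3 lists bound less often it was 3 of 309 genes without a word (0.971%). The odds ratio without a word was 174.1 (interval 55.1 to 868.1), for lists chosen by their own calls. Open promoters recovered with any antibody remain possible, since no library of untagged embryos was analysed here, and no biological explanation was tested.

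Replicate 2 had the highest promoter share among its 5190 strongest peaks, at 69.3% against 59.5% and 63.7%. Among the 1000 strongest peaks the libraries lay within 2.70 points, at 70.6%, 73.3% and 71.7%, but among the 2595 strongest they lay 6.74 points apart, at 67.2%, 73.9% and 70.5%, out of 9.83 points in the full lists. Weak peaks at the end of the other lists may therefore be part of the gap, and these values do not decide how much. With 3 libraries of 1 group, no biological explanation was tested.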

How the results depend on the processing

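Tests without repeats, without divergent genes, without core promoter words, of the 1000 strongest peaks and of distal peaks alone were chosen after the data were seen. Of 36 values of the main results that have a p, 35 kept their direction and their side of the threshold, and of 38 counts of calls 22 were the same as in the main results, which does not show that the same items were called. The combined relaxed list moved nothing, since its strongest peaks are the IDR peaks themselves, and its values in these counts could not change. Using the upper 50 percent of IDR peaks left 9 of the 15 called gene sets, and the dm3 list left 0 called arms, as it has no Y. The pericentric ratio was 0.451 outside repeats and no longer past the threshold, the mean promoter share of the 1000 strongest peaks was 71.9%, and distal peaks alone left 4 called motifs. The flanks of distal peaks were not cleared of promoter peaks, which may account for part of that loss. Values reversed for GAGA with 200 bp windows (8.11%) and, in windows at gene starts, for TATA against unbound promoters (10.7%). Differences were lost, with a changed sign but an adjusted exact p of 1, for the embedded genes once pericentric genes were left out (0%, which removes nearly the whole list), for mitochondrial ribosomal proteins without divergent genes (17.6% against 18.1%), and in distal peaks for Zelda (1.12% against 1.06%) and Pho (3.64% against 3.69%). Except where the list's own construction shows it, the cause was not tested. With each replicate left out in turn, in shorter lists of 3687 to 3980 peaks, the promoter share ran from 63.8% to 69.2%, the pericentric ratio from 0.279 to 0.359, the called gene sets from 12 to 14, the called feature classes from 5 to 6, the called motifs from 10 to 11, the divergent share from 59.9% to 60.8% and the pairwise overlap from 71.0% to 76.7%. Of 888 promoter calls of named genes, 839 were the same, 42 were lost and 7 gained. The 888 include 111 calls in the combined list, which could not change. Depth is unknown, so an unbound promoter is one without a listed peak, not one shown to lack Lhr. No paired analysis was possible because the series has 1 group.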

Other observations

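The comparison of transposons and the test of a sequence word were chosen only after the data, and for the word its result on all arms, had been seen. Annotated transposons were nearly free of peaks. They held 33 IDR summits, or 0.636%, against 5.92% ± 0.572 (SD) for rotated peaks (p = 2.0e-04, two-sided permutation test, the smallest possible), and 0.854% ± 0.292 (SD, n = 3) of the strongest peaks in the libraries. INE-1 copies held 5 of these summits, G5, Rt1b and gypsy 3 each, and the telomeric element HeT-A 2. Reads from near-identical copies are hard to place, so these counts cover only copies that the authors' lists could resolve.

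In distal peaks of 2L and 2R, the 8-base word with the highest excess over flanks was CACTGAGA, in 28 of 677 peaks (4.14%) against 0.230% of flanking windows. A hypothesis is that it marks a class of distal sites. On 3L, 3R and X it was in 48 of 1166 distal peaks (4.12%) against 0.404% of flanks, an odds ratio of 10.6 (p = 7.3e-15, Fisher's exact test). This is no independent test, since the word had already been noticed in distal peaks of the whole genome. It was found in 3.84% ± 0.382 (SD, n = 3) of distal peaks of the libraries, and none of its IDR peaks lay in an annotated transposon. The strongest peak of the list, at X 796258 to 797111 in CG16989, holds it, as do peaks nearest to slp2 (2L 3832374 to 3832662), aop, edl and pnt, named here after their values were seen. What binds this word may be another protein, and nothing in these data tests it.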
